A study of Homo sapiens with 8 samples.

How the data were processed

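Poly(A) RNA of 8 libraries of N/TERT-2G keratinocytes was sequenced on an Illumina Genome Analyzer IIx, 1 library per lane, in 2 batches. The authors aligned the reads with TopHat 1.3.3 and deposited 1 table of RPKM values with 1 column per library and 3 decimals. The counting tool, genome build and gene annotation are not given in the sources used here. Batches were taken from the sample descriptions. The numbers of the replicates pair control and Tet libraries through the batches (correlation across genes of deviations from the group mean of 0.476, 0.314 and 0.338), so the number was tried as a block. Control and Tet libraries of batch 1 with different numbers gave 0.272 and 0.334, so this does not tell the number from batch. For the Tet+EGF libraries the correlations at the same number were -0.31, -0.263, -0.137 and -0.155, which gave no sign of pairing. With 2 libraries in that group the deviations mirror each other, so these values cannot settle it. For Tet+EGF the block leaves out batch and ties Tet+EGF replicate 2 to libraries of batch 1.

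Genes with an RPKM of at least 1 in at least 2 libraries were kept, which left 12567 of 21510, and log2(RPKM + 0.5) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on all 8 libraries with group and batch as terms. Adjusted p-values are Benjamini-Hochberg over the genes kept with a threshold of 0.05, two-sided. Fold changes come from this fit unless a batch is named, and the pseudocount shrinks those of low genes. A batch by Tet interaction was fitted likewise. Before the data were examined, 22 gene lists were written from general knowledge, and the groups, tests, alternatives and rule for named genes were fixed. Lists were tested with limma camera at a preset correlation of 0.01, with Benjamini-Hochberg over the 22 lists, then with an estimated correlation, and with fry, which asks whether a list moves on balance. With an estimated correlation 0 lists passed camera in each of the 3 comparisons, against 0, 2 and 3 at an unadjusted p under 0.05, while 16, 9 and 9 passed fry for Tet against control, Tet+EGF against Tet and Tet+EGF against control. Named genes are AREG, FOXM1, EGFR and other ERBB ligands past the filter, the 8 largest rises and 8 largest falls per comparison among called genes with a mean RPKM of at least 5 and 1 sign in each batch, and up to 4 members with the smallest p of each list past 0.05. Other genes are said to have been chosen after their values were seen.

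The fit was tested on simulated data with known changes in few genes. Noise and batch effects followed the model of the fit, so the rates found need not hold for the real libraries. Of genes changed 2-fold, 88.1% were recovered between Tet and control and 76.1% between Tet+EGF and Tet, and of those changed 1.5-fold 54.7% and 25.4%, with false calls at 6.05% and 5.28%. Relative depth was estimated from the steps between RPKM values, which are whole reads scaled by depth and length, and was recovered for 35 of 35 simulated pairs. On the real libraries 1 of 7 direct estimates was off by a factor of 2, so the median of routes through another library was used.

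After genes that fell apart from their list were seen, all 7-base words in 3' UTRs were scored for lower expression of the genes that hold them, on 10193 genes with a 3' UTR of at least 100 bases in the GENCODE v29 annotation of GRCh38. Its prediction was written before the scan, which was first run in an exploratory version of the same design. It recovered 10 of 10 planted words. AREG itself was left out, and symbols of 2373 other genes were not matched to a searched 3' UTR.

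Alternatives were pseudocounts of 0.1 and 1, no filter and a mean RPKM of at least 5, no batch term, only the 2 groups compared, the replicate block, quantile, median-ratio and upper-quartile scaling, eBayes without trend or robust, library weights, a threshold of 0.01 or a 2-fold minimum, each batch alone, and each library left out in turn. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.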

Results

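Messenger RNA was sequenced from N/TERT-2G cells, an immortalised human keratinocyte line, carrying a tetracycline-inducible short hairpin RNA against AREG, the gene for the EGF receptor ligand amphiregulin. Cells were collected at 60 h in 3 groups: 3 libraries without tetracycline (control), 3 with tetracycline at 1 µg/ml (Tet) and 2 with tetracycline and EGF at 20 ng/ml (Tet+EGF). Batch 1 held 2 control and 2 Tet libraries, and batch 2 held 1 control, 1 Tet and both Tet+EGF libraries. The RPKM table listed 21510 gene symbols, of which 12567 passed the filter on low values. Read counts per library were not used here, and relative depth, read from the steps between low values, ranged from 63.4% to 111% of the control replicate 1 library, and these steps leave a factor of 2 open. KRT5, a basal keratin, had the highest RPKM in each library, at 2.03% to 4.27% of the sum. Across genes, which are not independent replicates, libraries of the same group and batch correlated at 0.9895 to 0.9955, and those of the same group in different batches at 0.9534 to 0.9617. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples.

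AREG, the targeted gene, was low in all 5 libraries with tetracycline. Its RPKM was 315.6, 202.1 and 188.8 in the control libraries, 6.63, 16.7 and 16.2 in the Tet libraries, and 20.9 and 17.4 in the Tet+EGF libraries. The log2 fold change between Tet and control was -4.17 (SE 0.36, limma adjusted p = 0.000109), with -3.53 in batch 1 and -5.47 in batch 2, and the difference between batches passed its own test (interaction of -1.94, limma adjusted p = 0.000815). Between Tet+EGF and control it was -3.36 (limma adjusted p = 0.00249), and -2.07 without the control replicate 1 library. Between Tet+EGF and Tet the value of 0.81 (SE 0.47) did not pass (limma adjusted p = 0.288). That value was 1.46 without the control replicate 1 library, where it passed (limma adjusted p = 0.00011), and -0.49 without the Tet replicate 1 library.

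**Figure D1:**
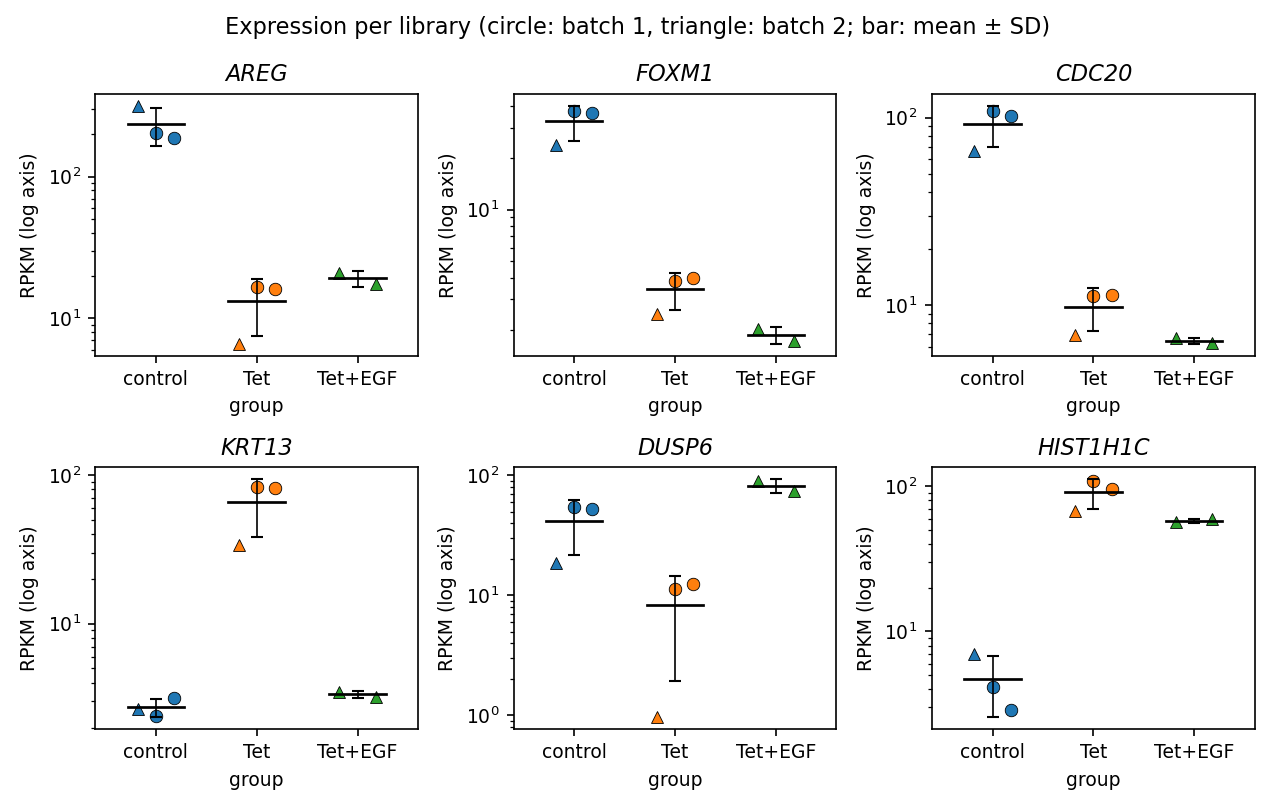
RPKM of AREG, FOXM1, CDC20, KRT13, DUSP6 and HIST1H1C on log axes in each control, Tet and Tet+EGF library, with circles for batch 1, triangles for batch 2 and bars for the mean ± SD of each group. FOXM1 was at 32.6 RPKM on average in control, 3.44 in Tet and 1.87 in Tet+EGF libraries.

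Induction of the hairpin was compared with control to ask what changed with it. FOXM1, a transcription factor of the cell division programme that the series title names, fell from 32.6 ± 7.57 to 3.44 ± 0.837 RPKM (SD, n = 3 in each group). Its log2 fold change was -3.06 (SE 0.08, limma adjusted p = 3.49e-06), with -3.08 in batch 1 and -3.03 in batch 2. Of 92 measured mitosis genes, 91 fell and 0 rose, and adjusted over the list alone the counts were the same. CDC20, an activator of the anaphase-promoting complex, fell by 3.17 on the log2 scale, PLK1, a mitotic kinase, by 2.63, and BIRC5, which encodes survivin and overlaps the EPR1 locus, by 2.63. CDC25B was the member that did not pass, at -0.10. The list median was -2.24, with -2.46 in batch 1 and -1.83 in batch 2 (limma camera adjusted p = 7.35e-29, adjusted p = 0.508 with an estimated correlation).

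The 3' UTR of FOXM1 held the 8-base sequence CCAAGTCA, which also occurs in the AREG mRNA. In FOXM1 it lay on chromosome 12 at 2858018 to 2858025 on the minus strand, and in AREG on chromosome 4 at 74454780 to 74454787 on the plus strand (GRCh38, GENCODE annotation). The AREG position is 3' UTR in the AREG-201 transcript and coding sequence in AREG-202. CCAAGTCA joins the 2 words with the strongest association with lower expression in the word scan of 10193 genes, FOXM1 among them. Their t was -11.14 and -11.03 for Tet against control. The sequence was searched for after the values of FOXM1 were seen. The sequence of the hairpin is not given in the sources used here, so whether the hairpin holds CCAAGTCA is not known. Of the 84 mitosis genes with a searched 3' UTR, 75 held neither 7-base word of it, and 74 of these 75 fell between Tet and control.

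Genes of DNA replication and the G1/S transition also fell. Of 72 measured, 66 fell and 1, CCND3, rose, and adjusted over the list alone 67 fell and 1 rose. CDC45, part of the replicative helicase, had a log2 fold change of -2.95, EXO1, an exonuclease, of -1.93 and RFC2, of the clamp loader, of -1.68. The median was -1.49, with -1.90 in batch 1 and -0.76 in batch 2 (limma camera adjusted p = 8.47e-14, adjusted p = 0.571 with an estimated correlation). Of 37 genes of the ATF4 and mitochondrial stress list, 30 fell and 2 rose, and adjusted over the list alone 30 fell and 3 rose. ASNS, asparagine synthetase, fell by 3.51, PYCR1, of proline synthesis, by 2.52 and SHMT2, of one-carbon metabolism, by 2.29. The median was -0.85 in batch 1 and -1.57 in batch 2 (limma camera adjusted p = 2.1e-07, adjusted p = 0.571 with an estimated correlation).

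Keratinocyte differentiation genes rose. Of 29 early differentiation genes, 24 rose and 0 fell, with the same counts adjusted over the list alone. KRT13, a suprabasal keratin, rose from 2.74 ± 0.375 to 65.8 ± 27.8 RPKM (SD, n = 3 in each group), LYPD3 rose by 3.03 on the log2 scale and SERPINB3, a serpin, by 1.99. The median was 1.55, with 1.72 in batch 1 and 0.80 in batch 2 (limma camera adjusted p = 9.27e-08, adjusted p = 0.508 with an estimated correlation). Of 62 late differentiation genes listed, 30 passed the filter on low values. Of these 30, 20 rose and 1, ALOXE3, fell, or 20 and 2 adjusted over the list alone. KLK5, a protease of the cornified layer, rose by 2.49 and PPL, which encodes periplakin, by 1.06. The median was 1.26 in batch 1 and 0.49 in batch 2 (limma camera adjusted p = 9.88e-06, adjusted p = 0.508 with an estimated correlation). Markers of fibroblasts moved in the same comparison: 6 of 9 measured rose and 2 fell, with the same counts adjusted over the list alone. DCN, a proteoglycan gene, rose from 0.0357 to 7.88 RPKM. The fibroblast list did not pass (limma camera adjusted p = 0.051), and it did pass without control replicate 2 (0.0433) or 3 (0.0331), Tet replicate 2 (0.034) or 3 (0.0463), or either Tet+EGF library (0.048 in each case).

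Transcripts of replication-dependent histone genes rose in these libraries of poly(A) RNA. Such libraries are not made to capture histone transcripts without a poly(A) tail, so the rise need not hold for those. Of 44 genes listed, 24 passed the filter on low values. Of these 24, 20 rose and 1, HIST1H2BH, fell, or 21 and 1 adjusted over the list alone. HIST1H2BK rose from 16.0 to 124.8 RPKM, HIST1H1C by 4.19 and HIST1H2BD by 3.08 on the log2 scale. The median was 1.86, with 2.12 in batch 1 and 1.26 in batch 2 (limma camera adjusted p = 2.68e-08, adjusted p = 0.508 with an estimated correlation). Among 190 tested small structural RNAs, which lack a poly(A) tail and were chosen after the histone values were seen, 10 rose and 26 fell, with a median of -0.26.

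Interferon response genes rose too. Of 50 measured, 35 rose and 1 fell, or 37 and 1 adjusted over the list alone. IFI6 rose by 1.41, TRIM22 by 1.08 and IFIH1, a sensor of double-stranded RNA, by 0.81. Of the 3 list members with a 7-base word of CCAAGTCA in a searched 3' UTR, 1 fell and 1 rose. The riser, at 2.01, held CCAAGTCA in full. OAS3, a 2'-5'-oligoadenylate synthetase gene, fell by 1.82, and its 3' UTR held both 7-base words of CCAAGTCA. The median was 0.64, with 0.62 in batch 1 and 0.79 in batch 2 (limma camera adjusted p = 4.08e-09, adjusted p = 0.508 with an estimated correlation). IFNB1, the gene for interferon beta, was at or below 0.175 RPKM in every library.

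Other lists moved less. Of 34 cell cycle inhibitor and p53 target genes, 18 rose and 4 fell, also adjusted over the list alone, with TP53I3 at 1.48 (limma camera adjusted p = 0.00251, adjusted p = 0.571 with an estimated correlation). Of 31 inflammatory and antimicrobial genes, 14 rose and 5 fell, also adjusted over the list alone, with SAA1, an acute-phase gene, at 2.79 (limma camera adjusted p = 0.00746, adjusted p = 0.749 with an estimated correlation). Their median was 1.22 in batch 1 and -0.19 in batch 2. Of 32 cholesterol synthesis genes, 15 rose and 2, SREBF2 and CYP51A1, fell, also adjusted over the list alone (limma camera adjusted p = 0.0143, adjusted p = 0.796 with an estimated correlation). That call was lost without the control replicate 1 library (0.382) and without the Tet replicate 1 library (0.362). Of 65 nuclear-encoded respiratory chain genes, 32 rose and 1 fell, also adjusted over the list alone (limma camera adjusted p = 2.54e-05, adjusted p = 0.575 with an estimated correlation). NDUFS4, a complex I subunit gene, was the faller at -1.61. Of 75 cytosolic ribosomal protein genes, 24 fell and 0 rose, and adjusted over the list alone 5 fell (limma camera adjusted p = 0.00746, adjusted p = 0.796 with an estimated correlation). The ribosomal call was lost without the control replicate 2 library (0.098), without the Tet replicate 3 library (0.0652), with median-ratio scaling (0.0579) and with upper-quartile scaling (0.171).

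The remaining lists did not pass camera, and their counts were the same adjusted over the list alone. By fry the basal (limma fry adjusted p = 0.0112), glycolysis (0.033), ERBB (0.0495), leukocyte (0.00244), endothelial (0.0271) and fibroblast (0.000307) lists passed. The direction by fry was higher for the fibroblast list and lower for the others. For the 3 endothelial genes it went against their median of 0.246 and mean of 0.481. The cholesterol synthesis (0.115) and ribosomal (0.0656) lists did not pass fry. In the basal and adhesion list 14 of 40 genes rose and 12 fell, in the wound and migration list 13 of 37 rose and 12 fell, and in the ERK feedback list 7 of 37 rose and 13 fell. In the basal list the median was -0.03 and the mean 0.02, and in the wound list the median was 0.02 and the mean -0.01. In the ERK feedback list the median was -0.187, with 0.101 in batch 1 and -0.845 in batch 2. DUSP6, an ERK phosphatase gene, fell by 2.65. In glycolysis and hypoxia 5 of 34 rose and 13 fell, and that list passed without the Tet replicate 1 library (0.00786) and without the control replicate 1 library (0.00703). ENO1, a glycolytic enzyme gene, fell by 2.03, and its 3' UTR held CCAAGTCA. Of 29 housekeeping genes 5 rose and 10 fell. Both leukocyte markers measured, CD68 and LCP1, fell, KDR rose and ENG fell among 3 endothelial markers, and the 1 melanocyte marker measured did not pass. Among 13 ERBB ligand and receptor genes 2 rose and 7 fell. EGFR fell by 1.08, TGFA by 1.22 and EREG by 1.46, and EPGN rose by 1.56, while HBEGF at -1.03 (limma adjusted p = 0.17) and NRG1 at 0.40 (limma adjusted p = 0.248) did not pass. Without the control replicate 1 library or the Tet replicate 1 library EREG was at -0.53 and HBEGF at 0.02. The call of EREG (limma adjusted p = 0.042) was lost without the Tet replicate 2 library (0.0569), the Tet replicate 3 library (0.0517), the control replicate 3 library (0.0583) or either Tet+EGF library (0.0628 and 0.0629). NRG1 passed at 0.90 without the control replicate 1 library (3.57e-05) or the Tet replicate 1 library (3.41e-05). The 3' UTR of TGFA held CCAAGTCA, and those of EGFR, EREG, EPGN and HBEGF held 1 of its 7-base words.

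Among all genes, the largest rises under the rule for named genes were of CXCL14, a chemokine gene, at 5.67, CYP1A1, an aryl hydrocarbon receptor target, at 4.89 and PRSS22, a serine protease gene, at 4.67. The largest falls included IL24, a cytokine gene, at -5.20, TFPI2, a protease inhibitor gene, at -4.17, TNFRSF6B, a decoy receptor gene, at -4.13 and STC2 at -3.95. NGFR, a neurotrophin receptor gene whose 3' UTR held CCAAGTCA, was at -3.52. With EGF added NGFR was higher by 2.66 than with Tet, and it was not called against control, at -0.865. Tetracycline was present in both the Tet and the Tet+EGF libraries. MT2A, a metallothionein gene, fell from 5279 to 350.9 RPKM. CDC25B, CCND3, ALOXE3, HIST1H2BH, OAS3, ENO1, DUSP6 in this comparison, KDR, ENG and the markers of other cell types were chosen after their values were seen.

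In total 3294 genes were higher and 3756 lower with Tet among 12567 tested (limma, Benjamini-Hochberg), of which 888 and 876 changed at least 2-fold. With the replicate number as a block in place of batch the counts were 2281 and 2530, and in batch 1 alone they were 3585 and 3682. The size of the change differed between batches for 3351 genes by the interaction test. That test rests on 1 control and 1 Tet library in batch 2. Both Tet+EGF libraries were in batch 2, so their comparisons in the main fit assume the same batch difference in each group. The genes called by the interaction test did not follow that assumption. In a fit without control replicate 1, the batch term rests on Tet replicate 1 as its only batch 2 library. In a fit without Tet replicate 1 it rests on control replicate 1 alike. Tetracycline and the hairpin were always given together, so the comparison of Tet with control does not separate them.

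**Figure D2:**
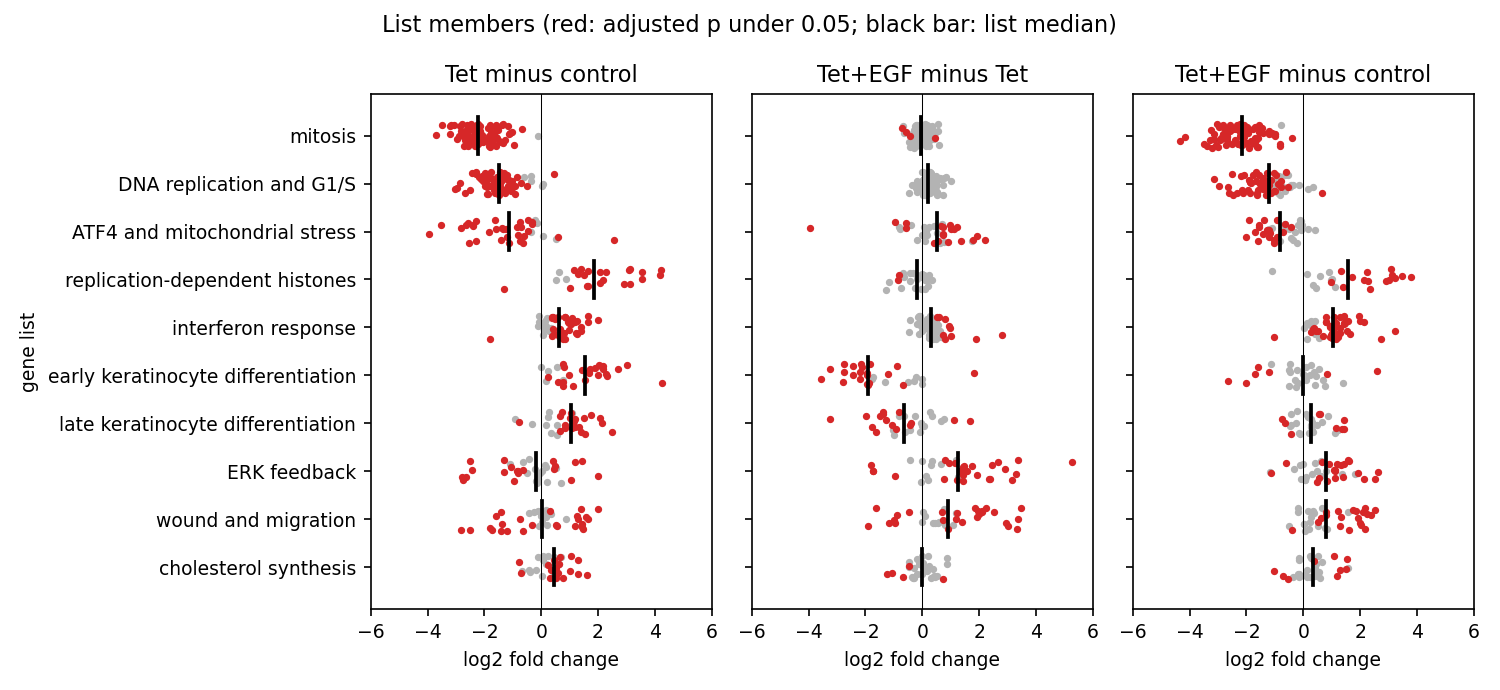
Log2 fold changes of the members of 10 gene lists in the 3 comparisons, each point a gene, red where the adjusted p was below 0.05, with a black bar at the list median. The mitosis list had medians of -2.24 for Tet against control, -0.03 for Tet+EGF against Tet and -2.17 for Tet+EGF against control.

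Tet+EGF was compared with Tet to ask what EGF changed in cells with the hairpin. ERK feedback genes, which are transcribed downstream of EGF receptor signalling, rose. Of 37 measured, 22 rose and 4 fell, or 25 and 5 adjusted over the list alone. DUSP6 was at 0.971 RPKM in the Tet library of batch 2, 11.4 and 12.5 in those of batch 1, and 89.8 and 74.4 with EGF. Its log2 fold change was 5.28, and 4.23 without the Tet replicate 1 library. HMGA1, a chromatin protein gene, rose by 1.14 on the log2 scale, while RGS2, a regulator of G protein signalling, fell by 1.81. The median was 1.25, and 1.60 within batch 2 (limma camera adjusted p = 1.78e-06, adjusted p = 0.676 with an estimated correlation), and 0.58 without the Tet replicate 1 library, which is the only Tet library of batch 2. Of 37 wound and migration genes, 19 rose and 7 fell, or 21 and 7 adjusted over the list alone. PTHLH rose by 3.36, PLAT, a plasminogen activator gene, by 2.23 and FN1, the fibronectin gene, by 1.95. The median was 0.89, and 1.13 within batch 2 (limma camera adjusted p = 4.63e-06, adjusted p = 0.378 with an estimated correlation).

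Differentiation genes fell with EGF. Of 29 early differentiation genes, 20 fell and 1, CST6, rose, or 21 and 1 adjusted over the list alone. LYPD3 fell by 2.18, SERPINB3 by 1.88 and KRT13 by 3.56. The median was -1.91, and -1.57 within batch 2 (limma camera adjusted p = 1.78e-11, adjusted p = 0.378 with an estimated correlation). Of 30 late differentiation genes, 13 fell and 2 rose, or 15 and 2 adjusted over the list alone, with KLK5 at -3.25 and PPL at -1.47. Their median was -0.63, and -0.37 within batch 2 (limma camera adjusted p = 0.000461, adjusted p = 0.676 with an estimated correlation). The fibroblast markers fell in 4 of 9 and rose in 1, or 5 and 1 adjusted over the list alone, with DCN at -4.00 (limma camera adjusted p = 0.00772, adjusted p = 0.378 with an estimated correlation). That call was lost without the Tet replicate 1 library (0.36) and among genes with a mean RPKM of at least 5 (0.183). Both leukocyte markers measured rose, also adjusted over the list alone, with CD68 at 1.65 (limma camera adjusted p = 0.00627, adjusted p = 0.378 with an estimated correlation). The leukocyte call was lost with no filter on low values (0.565). LCP1, the other marker, lost its call without either Tet+EGF library (0.0875 and 0.0778).

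Few mitosis genes moved with EGF. Of 92, 1 rose and 3 fell, and adjusted over the list alone 0 rose and 1 fell.
CENPO was the riser, and CDC25B, DEPDC1B and BIRC5 fell. The median was -0.03, and -0.22 within batch 2 (limma camera adjusted p = 0.279). At an unadjusted p under 0.05, 2 were higher and 7 lower. Whether the replicate numbers of the Tet+EGF libraries pair them with control or Tet libraries is not known. In comparisons with Tet+EGF the replicate block leaves out batch and ties Tet+EGF replicate 2 to libraries of batch 1. The list passed as lower with that block, at -0.25 (3.05e-05), and with no batch term, at -0.29 (4.69e-06). Without the Tet replicate 1 library the list was higher, with a median of 0.29 (0.000102), and without the control replicate 1 library it was lower, with a median of -0.22 (2.05e-05). FOXM1 differed by -0.32 (SE 0.11) and did not pass (limma adjusted p = 0.0854), and in a fit of batch 2 alone it passed at -0.34 (limma adjusted p = 0.0499), where the 1 Tet library was assumed to vary like the 2 Tet+EGF libraries. Of 72 DNA replication genes 0 passed in limma, also adjusted over the list alone, against 3 at an unadjusted p under 0.05, with a median of 0.22 (limma camera adjusted p = 0.0704). That list passed without the Tet replicate 1 library at 0.93 (6.29e-18) and without the Tet+EGF replicate 2 library at 0.27 (0.0209), and it was at -0.12 without the control replicate 1 library. CENPO, DEPDC1B, CDC25B, CST6 and, in this comparison, KRT13 were chosen after their values were seen.

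Interferon response genes rose further, 11 of 50 with 0 falling, or 14 and 0 adjusted over the list alone. CXCL11, a chemokine gene, rose by 2.82 and DDX58, an RNA sensor gene, by 0.94. The median was 0.29, and 0.20 within batch 2 (limma camera adjusted p = 0.000226, adjusted p = 0.676 with an estimated correlation). Of 37 ATF4 and mitochondrial stress genes, 15 rose and 4 fell, or 15 and 5 adjusted over the list alone, with ASNS at 1.79 and NUPR1 at -3.96 (limma camera adjusted p = 0.00422, adjusted p = 0.676 with an estimated correlation). That call was lost without the Tet replicate 1 library, at a median of 0.02 (0.684). Of 34 cell cycle inhibitor and p53 target genes 12 fell and 1 rose, also adjusted over the list alone, with FDXR at -1.07 (limma camera adjusted p = 0.00239, adjusted p = 0.676 with an estimated correlation). That call was lost with the replicate block (0.465) and with no batch term (0.932). Of 34 glycolysis and hypoxia genes 9 rose and 3 fell, or 9 and 4 adjusted over the list alone, with SLC16A3, a lactate transporter gene, at 2.13 (limma camera adjusted p = 0.0449, adjusted p = 0.676 with an estimated correlation). The glycolysis call was lost without control replicate 1 (0.852), 2 (0.0851) or 3 (0.0515), without Tet replicate 2 (0.101) or 3 (0.0989), and with the replicate block (0.147).

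Of 65 respiratory chain genes 5 fell and 0 rose, or 1 and 0 adjusted over the list alone, with NDUFB10 at -0.51 (limma camera adjusted p = 0.00239, adjusted p = 0.676 with an estimated correlation). Of 75 ribosomal protein genes 1, RPS19, fell, and 0 adjusted over the list alone (limma camera adjusted p = 0.00574, adjusted p = 0.676 with an estimated correlation). The ribosomal call was lost with the replicate block (0.925). By fry the ATF4 (limma fry adjusted p = 0.138), glycolysis (0.135), respiratory chain (0.237) and ribosomal (0.334) lists did not pass, and the basal list did (0.00333). Without the Tet replicate 1 library the ribosomal median was 0.02 and the respiratory chain list did not pass (0.573). RPS19 lost its call without control replicate 2 (0.0636) or 3 (0.0749), Tet replicate 2 (0.0588) or 3 (0.0561), or Tet+EGF replicate 1 (0.252) or 2 (0.127), and NDUFB10 without either Tet+EGF library (0.0532 and 0.0558). The other lists did not pass: in the basal and adhesion list 13 of 40 rose and 10 fell, or 16 and 12 adjusted over the list alone, and in the inflammatory list 9 of 31 rose and 8 fell, or 11 and 9 adjusted over the list alone. Of 24 histone genes 2 fell and 0 rose, or 0 adjusted over the list alone, of 32 cholesterol synthesis genes 1 rose and 4 fell, and of 29 housekeeping genes 4 rose and 0 fell, with the same counts for the latter lists adjusted over the list alone. Of 3 endothelial markers 1 rose, or 2 with 1 falling adjusted over the list alone, and the melanocyte marker passed only adjusted over the list alone. Histones passed without the Tet replicate 1 library, at -0.69 (0.00717), as did housekeeping genes at 0.31 (0.00155), and cholesterol synthesis passed without the control replicate 1 library, at -0.29 (6.76e-06). Of 13 ERBB genes 2 rose and 4 fell, or 5 and 4 adjusted over the list alone. EPGN fell by 2.36 and EGFR by 0.53, and the EGFR call was lost without control replicate 2 (0.0634) or 3 (0.0733), Tet replicate 2 (0.0588) or 3 (0.0672), or Tet+EGF replicate 1 (0.193) or 2 (0.129). EREG (limma adjusted p = 0.12), HBEGF (0.0606) and TGFA (0.0997) did not pass, and each passed without the control replicate 1 library (7.03e-06, 3.68e-05 and 9.69e-05). NRG1 did not pass (limma adjusted p = 0.455), and it passed without the Tet replicate 1 library, at -1.44.

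The largest rises included AKAP12, a kinase anchoring protein gene, at 5.64, TFPI2 at 5.43, TNFRSF6B at 5.39 and VIM, the vimentin gene, at 3.46. The largest falls included CXCL14 at -5.96, IGFL1 at -5.50, CXCR7 at -4.65 and H19, a noncoding RNA that is the host of MIR675, at -5.13. In total 1234 genes were higher and 1150 lower with EGF (limma, Benjamini-Hochberg). With the replicate number as a block the counts were 427 and 422, without Tet+EGF replicate 1 they were 385 and 427, without Tet+EGF replicate 2 they were 381 and 438, without control replicate 1 they were 2469 and 1764, and without Tet replicate 1 they were 2246 and 2633.

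**Figure D3:**
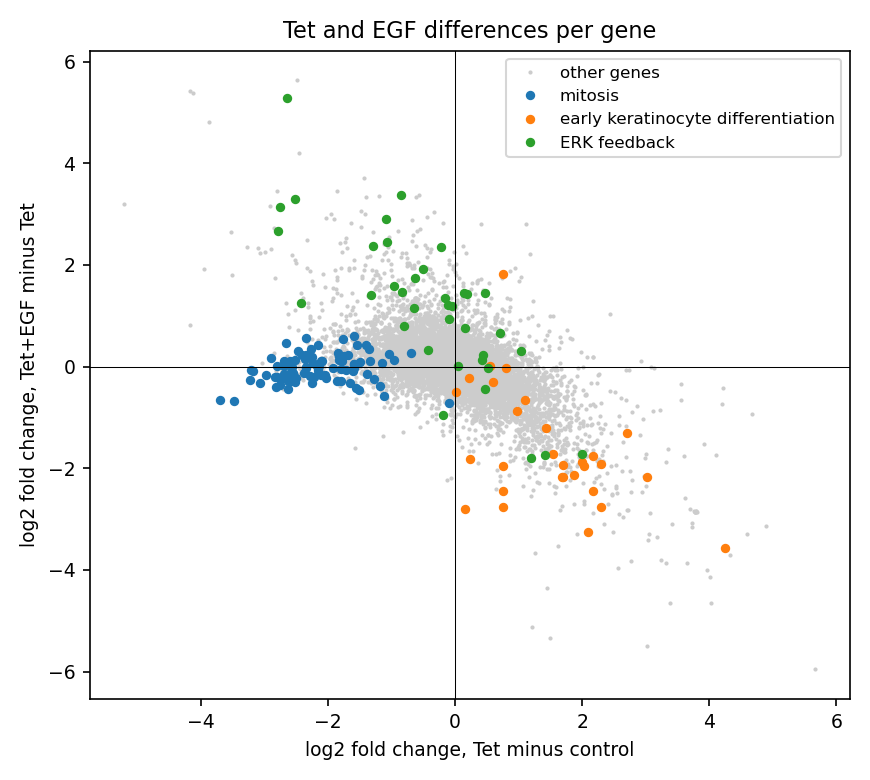
Log2 fold change of each gene for Tet against control on the horizontal axis and for Tet+EGF against Tet on the vertical axis, with mitosis, early differentiation and ERK feedback genes in colour. Mitosis genes lay at a median of -2.24 on the horizontal and -0.03 on the vertical axis.

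Many genes changed by Tet moved the other way with EGF. Of 3756 genes lower with Tet, 779 rose with EGF and 34 fell further, and of 3294 higher, 954 fell and 96 rose further. The total moved back was 1733, and independent calls would give 368.8 of the lower and 301.4 of the higher genes. Both comparisons share the Tet libraries, which alone gave opposite signs for 62.3% of genes in simulations of unchanged groups, against 68.6% observed. They were therefore also taken from different libraries. Of the 3585 genes higher in batch 1, 68.8% were lower with EGF than with Tet in batch 2, and of the 3682 lower in batch 1, 73.6% were higher, while 44.3% of all genes were lower. The total moved back was 631 with the replicate block, 665 without either Tet+EGF library, 2739 without control replicate 1 and 3243 without Tet replicate 1.

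Tet+EGF was compared with control to ask what remained of the difference when EGF was present. FOXM1 was lower by a log2 fold change of -3.38 (SE 0.11, limma adjusted p = 2.53e-05), and 90 of 92 mitosis genes were lower and 0 higher, or 92 and 0 adjusted over the list alone. CDC20 was at -3.26, PLK1 at -2.91 and AURKB, a kinase of chromosome segregation, at -3.28. The median was -2.17, and -1.99 within batch 2 (limma camera adjusted p = 4.49e-41, adjusted p = 0.31 with an estimated correlation). Of 72 DNA replication genes 48 were lower and 1 higher, or 55 and 1 adjusted over the list alone, with CDC45 at -3.14. Their median within batch 2 was -0.82 (limma camera adjusted p = 9.22e-15, adjusted p = 0.54 with an estimated correlation).

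Differentiation lists did not differ between Tet+EGF and control by the list test. Of 29 early genes 2 were higher and 5 lower, also adjusted over the list alone, with a median of 0.00 and a mean of -0.15 (limma camera adjusted p = 0.704). Of 30 late genes 6 were higher and 3 lower, also adjusted over the list alone (limma camera adjusted p = 0.157), and that list passed without the control replicate 1 library at 0.96 (0.000408). Interferon genes were higher in 41 of 50 and lower in 1, or 44 and 1 adjusted over the list alone, with DDX58 at 1.57. Their median was 1.04, and 1.12 within batch 2 (limma camera adjusted p = 1.06e-16, adjusted p = 0.31 with an estimated correlation). Histone genes were higher in 15 of 24 and lower in 0, or 17 and 0 adjusted over the list alone, with HIST1H2BK at 3.03 (limma camera adjusted p = 4.6e-08, adjusted p = 0.31 with an estimated correlation). Their median was 1.56, and 1.25 within batch 2.

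ERK feedback genes were higher in 19 of 37 and lower in 2, also adjusted over the list alone, with SPRY4, a signalling inhibitor gene, at 2.52 and a batch 2 median of 0.52 (limma camera adjusted p = 7.65e-05, adjusted p = 0.54 with an estimated correlation). Wound and migration genes were higher in 19 of 37 and lower in 1, or 21 and 1 adjusted over the list alone, with PLAU, a plasminogen activator gene, at 2.19 and a batch 2 median of 0.73 (limma camera adjusted p = 1.01e-07, adjusted p = 0.31 with an estimated correlation). Inflammatory genes were higher in 17 of 31 and lower in 3, or 19 and 3 adjusted over the list alone, with TNF at 2.06 and a batch 2 median of 0.61 (limma camera adjusted p = 0.000154, adjusted p = 0.54 with an estimated correlation). ATF4 and mitochondrial stress genes were lower in 19 of 37 and higher in 0, or 21 and 0 adjusted over the list alone, with ASNS at -1.72 and a batch 2 median of -1.05 (limma camera adjusted p = 1.98e-07, adjusted p = 0.54 with an estimated correlation). Ribosomal protein genes were lower in 20 of 75 and higher in 0, or 16 and 0 adjusted over the list alone, with RPS2 at -0.53 and a batch 2 median of -0.16 (limma camera adjusted p = 1.29e-06, adjusted p = 0.54 with an estimated correlation). With no batch term the ERK feedback call (0.142) and the ribosomal call (0.195) were lost. By fry the ERK feedback (limma fry adjusted p = 0.0719) and ribosomal (0.0513) lists did not pass. The other 11 lists did not pass camera, and of these the basal (0.0164) and leukocyte (0.00251) lists passed fry. In the basal and adhesion list 13 of 40 were higher and 7 lower, or 15 and 12 adjusted over the list alone, in glycolysis and hypoxia 5 of 34 and 6, or 6 and 6, and in the respiratory chain 11 of 65 and 2, or 0 and 1. Counts were the same adjusted over the list alone for cell cycle inhibitors and p53 targets (5 of 34 higher, 4 lower), cholesterol synthesis (6 of 32, 3), housekeeping (5 of 29, 4) and ERBB genes (0 of 13, 3). Of the markers of other cell types, 2 of 9 for fibroblasts were higher and 1 lower, 2 of 3 endothelial were higher and 1 lower, and the 1 melanocyte marker was higher, also adjusted over the list alone. Of 2 leukocyte markers 1 was higher, or both adjusted over the list alone. Among these lists the respiratory chain list passed without control replicate 2 (0.0173), Tet replicate 1 (0.00118) or 3 (0.0262) or Tet+EGF replicate 2 (0.0456), and cholesterol synthesis (3.39e-06), ERBB genes (0.0225) and leukocyte markers (0.0139) passed without Tet replicate 1. Cell cycle inhibitors and p53 targets passed without control replicate 1 (0.00499).

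Among all genes AKAP12 was higher by 3.16, and by 2.53 without the control replicate 1 library, and MYBL2, a cell cycle transcription factor gene, was at -4.35 and KIF20A, a kinesin gene, at -4.15. EGFR was at -1.62 (limma adjusted p = 0.00037). EREG at 0.29 (limma adjusted p = 0.772), HBEGF at 1.53 (0.171), TGFA at -0.33 (0.463), EPGN at -0.79 (0.0676) and NRG1 at -0.04 (0.941) did not pass. EREG at 2.14 and HBEGF at 3.64 passed without control replicate 1, where the batch term rests on Tet replicate 1. That library had EREG at 2.64 and HBEGF at 1.005 RPKM, against 12.8 and 12.8, and 5.64 and 8.20, in the batch 1 Tet libraries. The measured values differed less. EREG was at 17.7 to 30.8 RPKM in control and 18.6 to 20.5 in Tet+EGF libraries, and HBEGF at 6.4 to 12.8 and 16.1 to 19.9. Without Tet replicate 1 TGFA passed at -0.76, NRG1 at -0.54 and EPGN at -0.97, and EPGN passed at -0.89 without control replicate 2. CCL20, at 3.93, with values from 2.88 to 6.03 with each library left out, lost its call without the Tet+EGF replicate 1 library (0.0563). In total 2013 genes were higher and 2038 lower (limma, Benjamini-Hochberg), 1212 and 1083 with the replicate block, 740 and 845 without Tet+EGF replicate 1, and 778 and 870 without Tet+EGF replicate 2. Without Tet replicate 1 there were 3635 lower.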

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

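The replicate block on control and Tet libraries alone was chosen only after the data were seen, with 2401 genes higher and 2663 lower. The fold changes of AREG and FOXM1 between Tet and control kept direction and call under each alternative, and with each library left out ranged from -4.39 to -3.53 and from -3.08 to -3.05. FOXM1 between Tet+EGF and Tet ranged from -0.41 to -0.23, and passed in batch 2 alone at -0.34. Without a batch term, 2500 genes were lower with Tet, 635 higher and 528 lower for Tet+EGF against Tet, 1346 lower against control, and 821 moved back. With only the compared groups, EGF against Tet gave 2419 and 1786, and against control 3136 and 3870. The replicate block, which leaves out batch and ties Tet+EGF replicate 2 to batch 1 libraries, gave 427 and 422, 1212 and 1083, and 631 moved back. Library weights gave 468 and 507, 855 and 846, and 828. A threshold of 0.01 gave 506 and 532, 919 and 975, and 774. A 2-fold minimum, which removes smaller changes by construction, gave 888 and 876 for Tet, 351 and 440, 495 and 621, and 465. Batch 2 alone, with 1 control and 1 Tet library, gave 3393 and 2285, and 3590 and 4253. Lists past the threshold fell to 0 in each comparison with an estimated correlation. With each library left out, genes higher and lower ranged from 2719 to 3954 and 3181 to 4010 for Tet, 381 to 2469 and 427 to 2633 for EGF against Tet, 740 to 2946 and 845 to 3635 against control, and 665 to 3243 moved back. Lists past the threshold ranged from 12 to 13, 11 to 14 and 9 to 13. Directions that passed before or after the change turned for DNA replication in EGF against Tet without a batch term (-0.14), with only the compared groups (-0.12) and without control replicate 1 (-0.12), and for ribosomal proteins there without a batch term (0.11) and without Tet replicate 1 (0.02). Against control, EREG turned with only the compared groups and without Tet replicate 1 (both -0.64), and without control replicate 1 so did TGFA (0.53), NRG1 (0.96) and cholesterol synthesis (-0.24), while for glycolysis the list test turned to lower and its median kept its sign (-0.02, then -0.17). In EGF against Tet without Tet replicate 1, AREG (-0.49), mitosis (0.29), cholesterol synthesis (0.63) and the respiratory chain (0) turned. With each library left out, the ranges of these were -0.49 to 1.46 for AREG, -0.22 to 0.29 for mitosis, -0.12 to 0.93 for DNA replication, -0.29 to 0.63 for cholesterol synthesis and -0.21 to 0 for the respiratory chain in EGF against Tet, and -0.64 to 2.14 for EREG, -0.76 to 0.53 for TGFA, -0.54 to 0.96 for NRG1, -0.24 to 0.48 for cholesterol synthesis and -0.17 to 0.1 for glycolysis against control. Apart from the threshold and fold minimum, the cause was not tested. With no single library left out, 877 other list values were the same, 18 lost and 22 gained a call, and of named genes 2650, 117 and 15, and with 1 left out, 487, 11 and 23 of lists and 1433, 41 and 14 of named genes. A lone library in a group was assumed to vary like the others, and the comparison of separate libraries gives directions without a count. Depth limits low genes, and counts per library were not used here.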

Other observations

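The word scan, the tests of ERK feedback genes and of FOXM1's own site, and the ranges with each library left out were chosen only after related results were seen, and the families below after their values were seen. For the histone rise, tests of RNA without poly(A) and of library scaling were written down and withdrawn after some values of small structural RNAs were seen. Of 9 tested metallothionein genes, which bind metals and have similar sequences, 8 fell with Tet (median -2.89) and 8 rose with EGF (median 2.34). All 9 UGT1A genes, which encode glucuronidation enzymes and share exons, so that they are not separate measurements, rose with Tet (median 3.78) and fell with EGF (median -2.85).

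Mitosis genes stayed low when EGF was added. Within batch 2 the median between Tet+EGF and Tet was -0.224 (SE over 92 genes 0.029), which rests on 1 Tet library and was 0.29 in the fit without it, but against control the median lay between -2.65 and -1.99 with each library left out, which argues against batch. A lack of EGF action is opposed by ERK feedback genes, at 1.596 within batch 2 with the same Tet library (SE over 37 genes 0.268) and between 0.58 and 1.60 with each library left out. Silencing of each mitosis gene through a seed site in its 3' UTR is opposed by the 75 genes without one there. Their median was -2.144 against control (SE over genes 0.08). Words upstream of the 3' UTR were not counted for this, nor were other words with CAAGTC, such as CAAGTCT (t = -7.83 for Tet against control). Silencing of FOXM1 through its own site, with the others following, stays open, since 2.67% of those 75 genes (2) lay at or below FOXM1. With 1 hairpin, whose sequence is not given in the sources used here, it cannot be told apart from an effect of AREG loss, which is the biological explanation the design gives. An effect of tetracycline stays open too, as tetracycline and the hairpin were always given together.

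Single genes fell with Tet apart from their list. Of 16160 words scored, CCAAGTC had the strongest association with lower expression (t = -11.14, 963 genes, log2 shift of -0.303), and it occurs in the AREG mRNA, as do 7.18% of all words, while the lowest t in 100 permutations was -5.13 and words that share no 5-base run with it also passed that, among them TTTTTTA (-5.77) and TTTTTAA (-5.31). CCAAGTC ranked 1 in batch 1 and in batch 2 alone, and between Tet+EGF and Tet its t was -0.23. Between Tet+EGF and control its t was -13.61. There the strongest word without a shared 5-base run, TTTTTTA at -4.63, did not pass the lowest permuted t of -4.9. The hairpin's sequence is not known here, so silencing through a seed inferred from this word is only a candidate explanation for part of these falls, among them ENO1 (-2.03) and OAS3 (-1.82), chosen after their values were seen. NDUFS4 has no such word in its 3' UTR of 119 bases and 1 upstream of it. With Tet 44.2% of the 1673 genes with either 7-base word of CCAAGTCA were lower (740, with 316 higher). Of the 8520 with neither, 28.1% were lower (2390, with 2463 higher). Those 8520 may hold other words with CAAGTC, such as CAAGTCT (t = -7.83) and TCAAGTC (-7.26), which also passed the lowest permuted t. Of the 326 with CCAAGTCA 50.6% were lower (165, with 47 higher). Of the 1347 with a 7-base word but not CCAAGTCA 42.7% were lower (575, with 269 higher). By list, of 7 cholesterol synthesis genes with a word 0 were lower and 4 higher, and of 5 glycolysis and hypoxia genes 2 and 1.

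Interferon response genes were higher with Tet. Batch alone is opposed by the lower of the within-batch medians, 0.617 (SE over 50 genes 0.09). The SEs over genes, here and for mitosis and ERK feedback genes above, treat genes of a list as independent. The estimated correlations were 0.255, 0.449 and 0.431, and these SEs do not measure the spread between libraries. Sensing of the hairpin RNA may contribute. The 8 direct IRF3 targets had a median 0.55 above the other 42 genes, which met the bound of 0.5 set before. It did so by less than its SE over genes of 0.302, a margin not part of the prediction, and sensing is left open. An effect of AREG loss or of tetracycline stays open as well, as the design gives them together.

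For genes higher and lower with Tet, the 6 control and Tet libraries have 10 splits, too few for a share under 0.05. The real split, 1 of 10, gave 2877 and 3255 genes, and the highest other gave 0 in both directions.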
